A study of Arabidopsis thaliana with 7 samples.

How the data were processed

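Transcript levels were measured in seedlings of Arabidopsis thaliana, accession Ler-0, on 7 Affymetrix ATH1 arrays. Per the labels' protocols, plants were grown for 14 days on Murashige and Skoog medium at 24 °C, 30% relative humidity and a photoperiod of 16 h, and were then kept for 21 days on medium with 0, 40 or 80 mg/L cadmium sulfide quantum dots (CdS QDs), nanometre-sized crystals of a cadmium salt. RNA came from 0.1 g of plant material per sample, 100 ng of total RNA was amplified with the 3' IVT Express chemistry, and 15 µg of biotin-labelled aRNA was fragmented. The lines were WT and the mutants atnp01 and atnp02, which the labels describe as selected for resistance to CdS QDs. The genes disrupted in these mutants are not given in the sources used here.

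The deposited values are on a log2 scale, and were made with Affymetrix Expression Console 1.1 and RMA per the submitters' processing notes. The background step, the probe-set definition and whether another step followed RMA are not given in the sources used here. Array medians lay between 3.39 and 3.48, the lowest value was 0.31 and the highest 12.13. Not counting the first of each set, between 5344 and 6290 values of an array repeated another value of that array. Small differences between dim probe sets were therefore not interpreted. The low minimum and the repeated values leave open whether these are plain RMA values, and a further step would change what a log2 difference means as a fold. Each group had 1 array, and the number of arrays limits the precision of every value.

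Of the 22810 probe sets, 64 were controls and were kept out of all gene comparisons. The platform annotation listed 14016 of the others, of which 13513 had 1 gene and 503 had several. The remaining 8730 were unnamed here. Gene identifiers were matched to the gene table of assembly TAIR10.1, which supplied symbols and gene order, for 13436 of the 13513 probe sets, and 77 had no match. This left 13356 genes, of which 11809 had no symbol and are called by their locus code. For 146 genes with several probe sets, the probe set with the highest mean over the 7 arrays stood for the gene. The floor for a gene was log2 6 on the brighter array of a pair, a level that 20.6% of the non-control probe sets reached on their brightest array.

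The groups, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. For pairs of single arrays, genes with a log2 difference of at least 1, taken as 2-fold, were counted, with no p-value. For effects shared by the lines, limma 3.58.1 (R 4.3.3) was fitted to the 6 arrays at 0 and 80 mg/L, with line and dose as terms, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment at 0.05. Genes whose brightest of these arrays reached log2 6 were tested, 2106 in all. This fit had 2 residual degrees of freedom. Before moderation, its error is the spread of the response among the 3 lines, not the spread among plants of 1 line. Moderation then draws a gene's error towards that of genes of like mean intensity. For AT2G15560 in atnp01 against WT, the SE was 1.38 with the trend and 0.12 without it. Handling shared by the exposed arrays cannot be told apart from the exposure. A further model with a mutant-by-dose term had 1 residual degree of freedom. It took the 2 mutants as replicates of 1 class, and before moderation its error is the difference between their responses. Tables were handled in Python 3.11.15 with pandas 2.3.3.

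There were 24 gene lists with 496 entries, of which 81 were on the annotation and 39 reached the floor on some array, so that most lists are represented by few members. Lists of plastid-encoded and mitochondrion-encoded genes, and a count of genes 2-fold apart between WT at 80 and 40 mg/L, whose direct difference was planned, were added after the data were examined. For pairs of arrays, a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Across lines, lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. In single comparisons the genes named are the 10 highest and the 10 lowest, or fewer where fewer were counted, and limma results were named in the same way. The rule for lists was up to 4 members each, and the text names more for some lists, such as those of photosynthesis and plastid-encoded genes.

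The tests were checked on simulated data with 200 genes of known change among 2106. The fit found 98.8% of genes changed by log2 1 for the effect of 80 mg/L, with 6.2% false among its calls. For the line effects it found 98% for atnp01 and 98.7% for atnp02, with 5.4% and 6.1% false. The mutant-by-dose term recovered 96% with 6.9% false. The simulated noise was drawn independently for each gene at the variance that the same fit had estimated. These rates therefore hold only where that variance is right, and do not show how many real changes of this size were found. The percentile test placed 0% of unshifted lists of 8 genes in the upper tail, 92.5% of those shifted by log2 0.5 and 100% of those shifted by log2 1. Each of these rates came from 40 lists of random genes with independent noise. They do not cover lists of 3 members, or lists whose members change together. Alternatives covered the fold threshold, the floor, the normalization, the probe sets used, the variance model, the arrays in the fit and each line left out in turn.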

Results

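The study asked how transcript levels in Arabidopsis seedlings respond to CdS QDs, and how 2 mutants selected for resistance differ from WT. WT seedlings were measured at 0, 40 and 80 mg/L, the last being the minimum inhibitory concentration for WT per the labels. The mutants atnp01 and atnp02 were measured at 0 and 80 mg/L. There were no replicates, so each group is 1 array and differences between single arrays carry no error estimate. All values are log2 as deposited, and a difference of 1 is taken as 2-fold. Among the genes named from pairs of arrays, BGLU28, AT5G05250, AT1G47400, AT1G12030, AT5G22430, AT5G17340 and AT2G15560 had a dimmer value below log2 2 in at least 1 pair. Such values lay near background, so these differences have no exact size, nor do coefficients that average them. Between 3788 and 3889 probe sets per array were at log2 6 or above. Pearson correlations between arrays, across probe sets, ranged from 0.968 to 0.995.

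In WT, the 80 mg/L array showed much higher levels of a sulfur-limitation marker, an iron-deficiency peptide gene and defensin genes than the array without QDs, and lower levels of a copper chaperone and of glucosinolate genes. BGLU28, a glucosidase gene that marks sulfur limitation, was at 1.62 without QDs and at 7.95 at 80 mg/L, a difference of 6.33 from a value near background. AT5G05250 was higher by 5.15, and AT1G47400, which encodes a short peptide of the iron-deficiency response, by 4.94. The defensin genes PDF1.2b and PDF1.2, markers of ethylene and jasmonate signalling, were higher by 4.43 and 3.51. PDF1.2b was read on an _x_at probe set, a type whose probes may also match related sequences. The 2 genes may therefore not be separate readings. CCS, the copper chaperone of superoxide dismutase, differed by -2.66.

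In all, 156 genes were at least 2-fold apart between WT at 80 and at 0 mg/L, 108 of them higher and 48 lower. The next highest differences were those of AT1G66850 (3.39), AT1G56300 (3.27), AT3G56360 (3.24), AT1G62760 (3.11) and the sugar-transporter gene AT3G05400 (3.0). Among the genes with lower levels, the chitinase-family gene AT2G43620 differed by -3.30, the methionine sulfoxide reductase gene MSRB6 by -2.89 and AOP3, of glucosinolate side-chain modification, by -2.69. OCT1, of the organic cation transporter family, differed by -2.58, the glutathione transferase gene GSTU20 by -2.29 and the ATP sulfurylase gene APS4 by -2.14. AT1G29660, AT4G22490 and AT5G12050 completed the list at -2.02, -2.01 and -1.96.

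Several gene lists stood apart from random lists in this pair of arrays. The 3 genes of reactive oxygen scavenging on the annotation, which all reached the floor, had a median of -0.981, at percentile 0.3 of the random lists. The 3 glucosinolate genes on the annotation had a median of -1.081 at percentile 0.1, with BCAT4, of methionine chain elongation, at -1.79 and AT2G31790 at -1.08. Of 40 photosynthesis genes on the list, all encoded in the nucleus, the 8 on the annotation had a median of -0.32 at percentile 0.3, and none was 2-fold apart. Of 6 annotated genes of expansins and xyloglucan endotransglucosylases, the 3 that reached the floor had a median of -0.553 at percentile 0.7, and over all 6 the median was -0.743. Of 69 annotated plastid-encoded genes, the 48 that reached the floor lay in the other direction, with a median of 0.581, at percentile 100, and 19 of them were at least 2-fold higher. Over all 69 the median was 0.46.

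At 40 mg/L, WT showed higher levels of many of the same genes, while the iron-deficiency peptide gene and a cold-response gene did not follow. BGLU28 was higher than at 0 mg/L by 7.27, PDF1.2b by 2.9, the alpha-amylase gene AMY1 by 2.84, the peroxidase gene Prx37 by 2.69 and the senescence-associated gene SAG29 by 2.59. AT1G47400 was at 1.07 without QDs, at 1.01 at 40 mg/L and at 6.01 at 80 mg/L. The first 2 of these values lay below their arrays' lower quartiles of 1.32 and 1.29. COR15B, a cold-regulated gene, was at 3.44, 3.08 and 6.39. Other high differences at 40 mg/L were those of AT1G12030 (4.2), AT3G05400 (3.64), AT1G62760 (3.50), the peroxidase-family gene AT5G19890 (3.29) and AT4G31330 (3.27).

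Of the 142 genes at least 2-fold apart at 40 mg/L, 96 were higher and 46 lower. MSRB6 differed by -3.45, AT2G43620 by -2.54, AT5G12050 by -2.06, AT4G16980 by -2.03 and APS4 by -1.90. AT5G62280, AT1G60590, AT2G10940, AT5G63180 and AT5G55450 followed, at -1.82, -1.77, -1.73, -1.64 and -1.64. The reactive oxygen list had a median of -0.5 at percentile 2.5, the photosynthesis list of -0.329 at percentile 0.8, and the plastid-encoded genes of 0.503 at percentile 100, or of 0.621 over all 69.

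The 80 and 40 mg/L arrays were 2-fold apart for 46 genes, 37 of them higher at 80 mg/L, a count added after the data were examined. These included AT1G47400 (5.0, against a 40 mg/L value near background), AT5G05250 (3.61), COR15B (3.30), AT1G56300 (2.93), AT4G16146 (2.45), AT2G16005 (2.27), AT5G62720 (2.13) and the protochlorophyllide reductase gene PORB (1.98). AOP3 differed by -1.50 and GSTU20 by -1.39. Across 2001 genes, the differences at 40 and at 80 mg/L correlated at r = 0.805, where 0.485 came from simulated unchanged groups that share the control array. The covariance was 0.3106 against 0.0191 simulated, a difference of 0.2915. The 2 doses shared 71 of the higher and 27 of the lower genes, where independent lists would share 5.8 and 1.2 and simulated unchanged groups 1.4 in all. Part of this excess may come from the shared control array, and genes are not independent replicates.

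**Figure D1:**
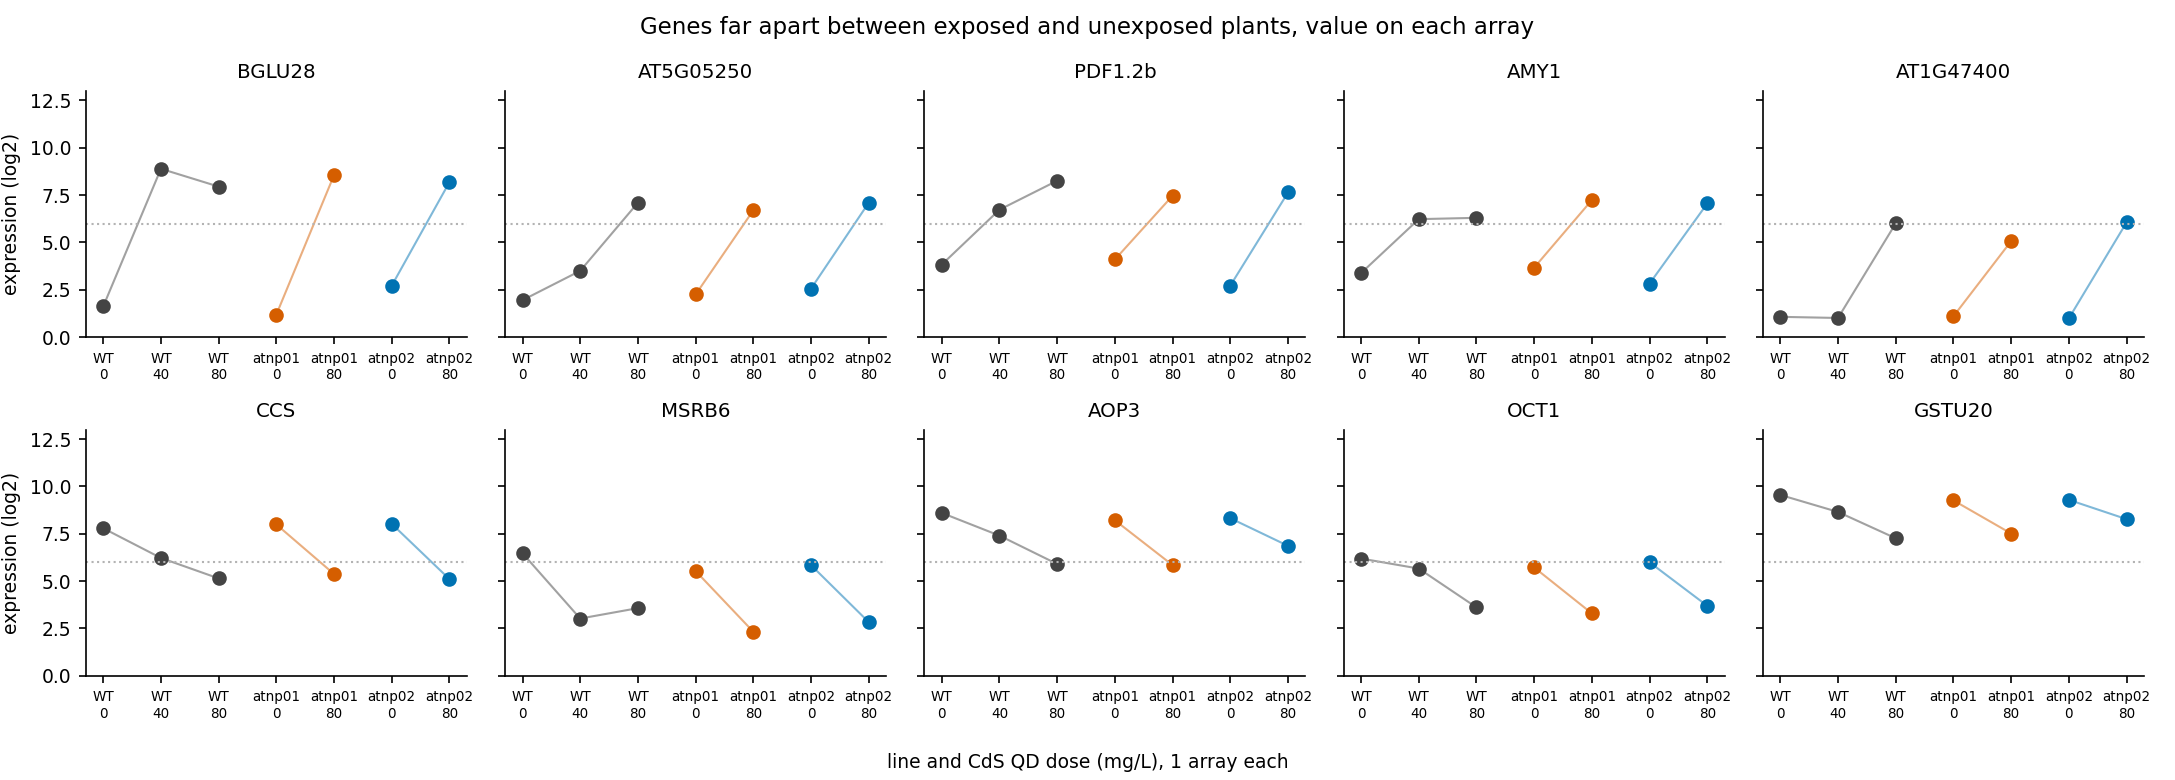
Expression (log2, y axis) of 10 genes on each of the 7 arrays (x axis, line and dose in mg/L). Each point is 1 array, lines join the doses of a plant line, and the dotted line is the floor of log2 6. BGLU28 was at 1.62 in WT without QDs and at 7.95 at 80 mg/L, while CCS went from 7.79 to 5.14.

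In atnp01, the sulfur-limitation marker BGLU28, the amylase gene AMY1, a defensin gene and 2 plastid ribosomal protein genes were far higher at 80 than at 0 mg/L. BGLU28 was higher by 7.37, from a value of 1.19 that lay below the lower quartile of 1.29. AT5G05250 was higher by 4.46, AT3G05400 by 3.87, AT1G62760 by 3.58, AT1G30700 by 3.57, AMY1 by 3.57, PDF1.2b by 3.37 and the chitinase-family gene AT2G43590 by 3.19. The plastid genes rpl16 and rpl14 were higher by 3.18 and 3.17. The wall-loosening expansin gene EXPA8 was lower, with a difference of -2.21.

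There were 224 genes at least 2-fold apart in atnp01, 147 higher and 77 lower at 80 mg/L. The lowest differences were those of AT1G60590 (-2.72), CCS (-2.62), AT5G62280 (-2.47), AT2G21045 (-2.45), AOP3 (-2.37), AT1G29660 (-2.29) and AT4G33550 (-2.26), followed by EXPA8 and then by AT2G34620 (-2.15) and AT2G10940 (-2.14). The reactive oxygen list had a median of -0.777 at percentile 1.3, the glucosinolate list of -0.939 at percentile 0.4 and the expansin and xyloglucan endotransglucosylase list of -0.825 at percentile 0.5. The plastid-encoded genes had a median of 1.055 at percentile 100, with 26 of the 48 at least 2-fold higher, and of 0.899 over all 69.

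In atnp02, the 4 genes with the highest differences at 80 mg/L were those of WT. BGLU28 was higher by 5.47, AT1G47400 by 5.07 from a value near background, PDF1.2b by 4.92 and AT5G05250 by 4.54. AT5G22430 (4.45), AT2G20870 (4.37), AT1G62760 (4.36), AMY1 (4.23), AT2G43590 (3.92) and AT1G30700 (3.86) came next. Among the lower genes, AT5G17340 differed by -4.65, AT1G73120 by -2.97, CCS by -2.92, the lipase-family gene AT1G29660 by -2.65 and AT2G43620 by -2.49.

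There were 222 genes at least 2-fold apart in atnp02, 150 higher and 72 lower. AT5G01740, AT5G44020, AT4G30170, AT4G29020 and AT1G31710 completed the lowest 10, at -2.47, -2.43, -2.43, -2.28 and -2.28. The expansin and xyloglucan endotransglucosylase list had a median of -1.459 at percentile 0.1, or of -0.839 over all 6 annotated members, the reactive oxygen list of -0.72 at percentile 1.4, and the plastid-encoded genes of 0.832 at percentile 100, with 20 of the 48 at least 2-fold higher. Over all 69 plastid-encoded genes the median was 0.579.

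Across the 3 lines, the sulfur-limitation marker BGLU28, defensin genes and the amylase gene AMY1 rose at 80 mg/L, and the copper chaperone gene CCS, the ATP sulfurylase gene APS4 and the glucosinolate gene BCAT4 fell. In the limma fit, BGLU28 rose by 6.39 (SE 0.35, adjusted p = 4.6e-05), PDF1.2b by 4.24 (SE 0.26) and AMY1 by 3.57 (SE 0.27). The size for BGLU28 is not exact, because its WT and atnp01 values at 0 mg/L lay near background. CCS fell by 2.73 (SE 0.08, adjusted p = 1.1e-05), and it was lower in 3 of 3 lines. APS4 fell by 2.07 and BCAT4 fell by 1.36.

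The fit placed 1202 of 2106 genes at adjusted p under 0.05, with 585 higher and 617 lower at 80 mg/L, while after loess normalization 632 were higher and 541 lower. AT5G05250 rose by 4.71, AT1G62760 by 3.69, AT2G43590 by 3.31, AT1G56300 and AT3G05400 by 3.29 each, AT1G30700 by 3.27 and AT5G19890 by 3.17. On the other side AT5G17340 had a coefficient of -3.85 (SE 1.1, adjusted p = 0.0224), MSRB6 of -3.04, AT2G43620 of -2.55, OCT1 of -2.44 and AT1G72230 of -2.36. AT5G12050, AT4G22490, AT1G29660 and the peroxidase-family gene AT4G30170 had coefficients of -2.34, -2.33, -2.32 and -2.17. AT1G47400, at 4.66 (SE 2.05) from unexposed values near background, missed the threshold with an adjusted p of 0.0906. The count was 798 without the atnp01 arrays, and the call of AT4G22490 was lost without atnp02. That of AT5G17340 was lost without WT or atnp01, with the WT 40 mg/L array counted as exposed and with a linear dose term. Poly-A spike-in controls, which measure amplification, differed between 80 and 0 mg/L by a mean of -0.40 in WT, -0.72 in atnp01 and -0.48 in atnp02, and hybridization controls by -0.10, -0.16 and -0.01.

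Of all 2106 tested genes 617 fell and 585 rose, so a call of a single list member is not unusual. Among the lists fixed in advance, reactive oxygen scavenging had 26 entries. All 3 of its genes on the annotation fell, over all genes and adjusted over the list alone. Besides CCS, the chloroplast ascorbate peroxidase genes SAPX and TAPX had coefficients of -0.83 and -0.50. In camera this list had an adjusted p of 0.0263, and an adjusted p of 0.618 with an estimated correlation, and fry gave an adjusted p of 0.00401. Of 4 annotated sulfur genes 3 reached the floor, and of these BGLU28 rose while APS4 and the sulfite reductase gene SIR (-0.46) fell, also adjusted over the list alone. The median of that list was -0.46 and its mean 1.29, its camera adjusted p was 0.537, and its fry adjusted p was 0.0243, both tests having the direction of the median. Both defensin genes rose, PDF1.2 by 2.81 and PDF1.2b on its _x_at probe set. Of 5 annotated cold-response genes 3 reached the floor, and COR15B (2.69), COR47 (0.59) and LTI30 (0.39) rose, with a camera adjusted p of 0.062 and a fry adjusted p of 0.0243. With the WT 40 mg/L array counted as exposed, COR15B, LTI30 and SIR no longer passed, and LTI30 was also lost without the atnp02 arrays and with a linear dose term.

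Of the 8 annotated photosynthesis genes, from a list of 40, 1 rose and 6 fell, and the counts adjusted over the list alone were equal. LHCB4.3, of the light-harvesting antenna, rose by 1.09, while LHCB4.2 (-0.79), the photosystem I gene PSAN (-0.45) and the photosystem II gene PSBY (-0.40) fell. The calls of RCA and LHCB4.1, which also fell, were lost in several alternative fits, loess normalization among them, and that of SBPASE without the atnp01 arrays and with a linear dose term. The camera adjusted p was 0.0832 and the fry adjusted p 0.015. Of 3 glucosinolate genes 2 fell, BCAT4 and the glucosyltransferase gene AT2G31790 (-0.86), with UGT74B1 at -0.16, a camera adjusted p of 0.0976 and a fry adjusted p of 0.0647. Of the 3 expansin and xyloglucan endotransglucosylase genes that reached the floor, EXPA8 fell by 1.81 and XTH19 fell by 0.91. EXPA4 differed by 0.46 in WT, -0.83 in atnp01 and -0.72 in atnp02, and had a coefficient of -0.36. Without the WT arrays its coefficient was -0.77, and it passed. For this list the camera adjusted p was 0.128, and the fry adjusted p was 0.105. Counts adjusted over the list alone matched for both lists. XTH19 no longer passed without the line term or with the WT 40 mg/L array counted as exposed.

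Of 8 annotated glutathione transferase genes, the 4 that reached the floor split evenly, with GSTU16 (0.71) and GSTU27 (0.51) higher and GSTU20 (-1.68) and GSTU18 (-0.37) lower, all past the threshold. Their median was 0.07 and their mean -0.21, the camera adjusted p was 0.971, and the fry adjusted p was 0.377, both tests having the direction of the median. In the list of metal chelation and glutathione synthesis, the metallothionein gene MT1C rose by 0.22, and the glutathione reductase genes GR1 (-0.28) and GR (-0.49) fell, with a camera adjusted p of 0.537 and a fry adjusted p of 0.0423 for a decrease. The calls of MT1C and GR1 were lost in several alternative fits, that of GSTU27 with a linear dose term and that of AER with the WT 40 mg/L array counted as exposed. In the list of mitochondrial stress, of whose 8 annotated genes 3 reached the floor, AT2G21640 rose by 2.36 and the alkenal reductase gene AER by 0.52, and MSRB9 fell by 1.11, with a camera adjusted p of 0.537 and a fry adjusted p of 0.0366 for an increase. For these 3 lists the calls adjusted over the list alone equalled those over all genes. SAG29, the 1 of 3 annotated senescence genes that reached the floor, rose by 2.08. The root marker PYK10 had a coefficient of -0.25 (adjusted p = 0.00813, lost in 4 alternative fits, with loess normalization, with no floor, with the WT 40 mg/L array counted as exposed and with a linear dose term), and the reference genes GAPC2 and PEX4 of -0.01 and 0.01.

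Of 48 plastid-encoded genes that reached the floor, a list added after the data were examined, 33 rose and 1 fell at 80 mg/L, or 34 and 1 adjusted over the list alone, with a median of 0.84, and the others did not pass. The calls of rpl32, ndhC and psbA were lost in some alternative fits. The ribosomal protein genes rpl16 and rpl14 rose by 2.80 and 2.37, and the photosystem II genes psbN and psbC by 2.45 and 2.33. The NADH dehydrogenase gene ndhK rose by 2.24 and rps2 by 2.25, while ndhD fell by 1.17 (SE 0.07). The neighbouring genes psbE, psbF, psbL and psbJ had coefficients of 0.03, -0.05, 0.01 and 0.08, and none passed. The camera adjusted p was 5.45e-08, the adjusted p was 0.618 with an estimated correlation, and fry gave an adjusted p of 0.0302.

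**Figure D2:**
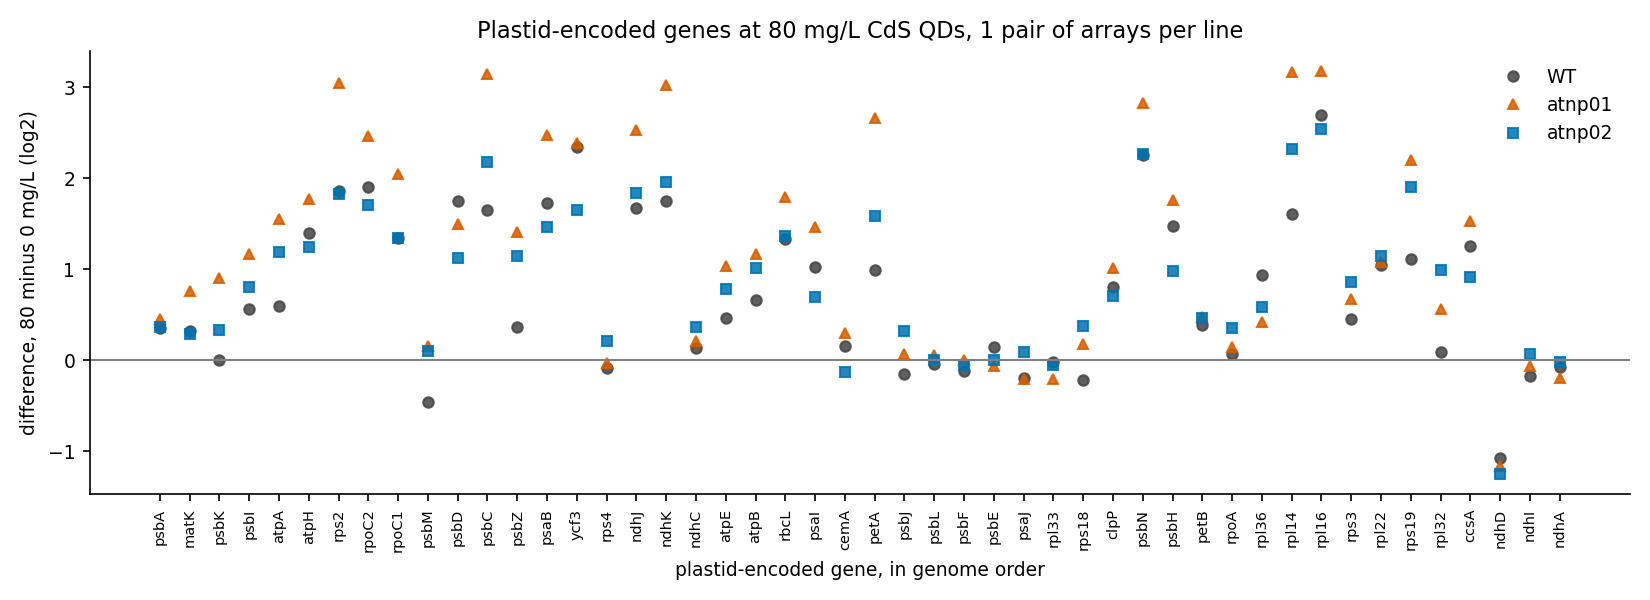
Difference between 80 and 0 mg/L (log2, y axis) for 48 plastid-encoded genes in genome order (x axis), with 1 point per line from 1 pair of arrays. rpl16 was higher by 2.70 in WT, 3.18 in atnp01 and 2.54 in atnp02, ndhD differed by -1.08, -1.16 and -1.25, and psbE lay near 0 in each line.

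The responses of the 3 lines overlapped widely. At 80 against 0 mg/L, 96 genes were at least 2-fold higher in all 3 lines and 43 lower, where independent lists would share 0.7 and 0.1. BGLU28, PDF1.2b, AMY1 and AT1G62760 were among the higher and CCS, AT1G29660 and MSRB6 among the lower genes. No gene was 2-fold apart in opposite directions in 2 lines. The log2 differences correlated across 2106 genes at r = 0.906 for WT and atnp01, 0.913 for WT and atnp02 and 0.917 for the mutants. These responses share no arrays.

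**Figure D3:**
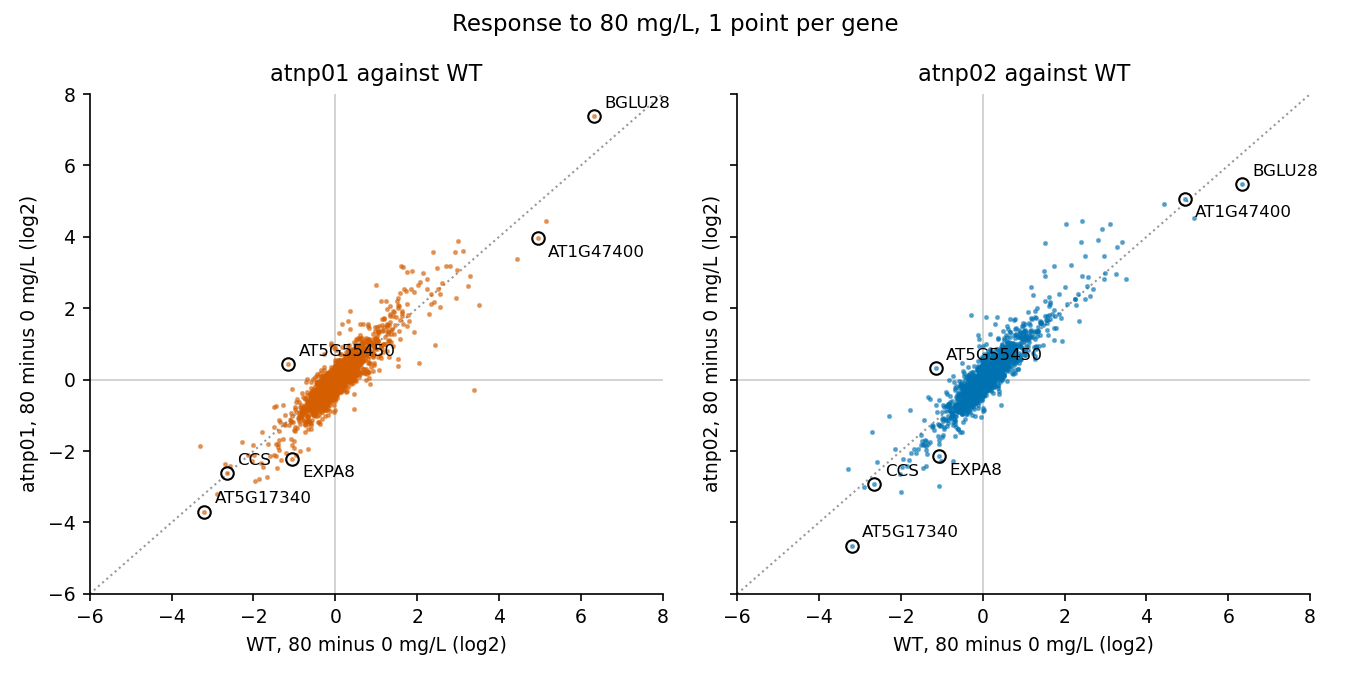
Difference between 80 and 0 mg/L (log2) in each mutant (y axis) against that in WT (x axis), 1 point per gene for 2106 genes, with equal values on the dotted line. BGLU28 lies far out in each line, with differences of no exact size in WT and atnp01, and AT5G55450 was lower at 80 mg/L in WT alone.

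Without QDs, both mutants lay close to WT. AT2G15560 stood out, at 7.13 in WT, 2.05 in atnp01 and 2.24 in atnp02, which are differences of -5.08 and -4.90. The glucose transporter gene SWEET1 was higher by 1.5 in atnp01 and by 1.14 in atnp02. AT1G13880 was higher by 1.98 in atnp01, where plastid genes such as psbC (-1.38) and petA (-1.36) had lower levels.

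In atnp01, 11 genes were 2-fold apart from WT at 0 mg/L, 3 higher and 8 lower. AT1G73600 was higher by 1.08, and AT4G22490 (-1.63), AT2G43620 (-1.20), AT5G48900 (-1.11), rpl14 (-1.11) and AT3G16530 (-1.08) were lower. In atnp02 there were 4 such genes, with AT4G30170 higher by 1.25 and AT2G16005 by 1.07 besides SWEET1 and AT2G15560. The plastid-encoded genes had medians of -0.311 in atnp01 and -0.343 in atnp02, both at percentile 0. The expansin and xyloglucan endotransglucosylase list had medians of -0.794 and -0.509, at percentiles 0 and 0.1, or of -0.389 and -0.343 over all 6 annotated members. The differences of the mutants from WT shared 2 genes and correlated at r = 0.6 across 1859 genes, where 0.489 came from simulated unchanged groups with the shared WT array. The covariance was 0.0322 against 0.0151 simulated.

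At 80 mg/L, both mutants had lower levels of the wall-loosening genes EXPA8 and XTH19 than WT and higher levels of CHI, CYP71B23, RING1 and AT5G55450. EXPA8 differed from WT by -1.94 in atnp01 and -1.59 in atnp02, and XTH19, a xyloglucan endotransglucosylase gene, by -1.11 and -1.49. CHI, of the chitinase family, was higher by 1.32 and 1.37, the cytochrome P450 gene CYP71B23 by 1.27 and 1.29, the ubiquitin ligase gene RING1 by 1.19 in both, and AT5G55450, of the lipid transfer protein family, by 1.85 and 1.29. AT2G15560 differed by -5.28 in both. SWEET1 was higher by 1.37 and 1.03.

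There were 25 genes 2-fold apart between atnp01 and WT at 80 mg/L, 11 higher and 14 lower. AT1G13880 was higher by 2.16, AT2G41090 by 1.08, AT3G23570 and AT1G65500 by 1.07 each and AT3G14280 by 1.02. AT1G66850 (-2.08), AT3G47160 (-1.56), AT5G11420 (-1.32), AT2G43590 (-1.20), AT5G22580 (-1.10), DRT100 (-1.07) and ycf3 (-1.06) were lower. For atnp02 there were 23, with 11 higher and 12 lower. AT4G19430 was higher by 1.81, AT5G33370 by 1.24, AT1G19960 by 1.09, ECS1 by 1.08 and AT2G20870 by 1.08. Of these, AT4G19430, AT5G33370 and AT2G20870 were higher on the atnp02 80 mg/L array than on each other array, by 1.51, 1.13 and 1.06, and that array also stood apart in other probe sets. The plastid genes ycf3 (-1.28), psbD (-1.20) and psbN (-1.05) were lower in atnp02, as were AT1G29660 (-1.14), AT5G22580 (-1.08), AT5G44020 (-1.04) and AT3G54400 (-1.04). The 3 wall-loosening genes that reached the floor had medians of -1.114 and -1.495, both at percentile 0. Over all 6 annotated members the medians were -0.887 and -0.447, with XTH18 higher by 0.43 and 0.08. The glucosinolate list in atnp02 had a median of 0.385 at percentile 99.3. The mutants' differences from WT shared 12 genes, 5 higher and 7 lower, where independent lists would share 0.1 in each direction and simulated unchanged groups 2.1 in all. They correlated at r = 0.718, against 0.494 simulated, and the covariance was 0.0615 against 0.0209, so that part of the excess may come from the shared WT array.

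Over both doses, SWEET1 was the gene that passed the test in both mutants. In limma it was higher than in WT by 1.43 in atnp01 (SE 0.09, adjusted p = 0.0017) and by 1.09 in atnp02 (SE 0.09, adjusted p = 0.0108), in 2 of 2 doses each. In atnp01, AT1G13880 was also higher by 2.07 (SE 0.14, adjusted p = 0.00177), and AT3G49220, of the pectinesterase family, had a coefficient of -0.86 (SE 0.10, adjusted p = 0.0373).

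These were 3 genes for atnp01 and 1 for atnp02 of 2106, with 199 and 145 at an unadjusted p under 0.05. Leaving out the other mutant gave 15 and 2 genes. Without the floor, the calls of AT3G49220 and of SWEET1 in atnp02 were lost, and that of AT3G49220 also without the intensity trend. AT2G15560, with coefficients of -5.18 and -5.09, had an SE of 1.38 and adjusted p of 0.26 and 0.46. Without the intensity trend the SE was 0.12 and the adjusted p 4.9e-05 and 5.41e-05. It also passed with no floor (adjusted p = 0.000339 and 0.000378), a floor of log2 4 (adjusted p = 8.09e-05 and 9.16e-05) and the other mutant left out (adjusted p = 0.0183 and 0.0201), but not with robust moderation, averaged probe sets, without _s_at and _x_at probe sets or after loess normalization. The expansin and xyloglucan endotransglucosylase list had a camera adjusted p of 0.00109 in atnp01 and 0.037 in atnp02, and adjusted p of 0.878 and 0.698 with an estimated correlation. Adjusted over the list alone, 2 of its 3 genes passed in each mutant, EXPA8 (-1.37 and -1.05) and XTH19 (-1.03 and -1.04), and none over all genes. The plastid-encoded genes had medians of -0.09 and -0.25, with camera adjusted p of 0.0051 and 4.97e-08, and again adjusted p of 0.878 and 0.698 with an estimated correlation. In single comparisons with WT, their medians were -0.311 in atnp01 and -0.343 in atnp02 at 0 mg/L, but 0.065 and -0.177 at 80 mg/L. In atnp02 the glucosinolate and sulfur lists, with medians of 0.19 and 0.21, each had a camera adjusted p of 0.037, and an adjusted p of 0.698 with an estimated correlation. For each of these lists fry gave an adjusted p of 0.813 in atnp01 or 0.538 in atnp02.

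With the 2 mutants taken as replicates of 1 class, the response to 80 mg/L differed from that of WT for 1 gene. Before moderation, the error of this fit is the difference between the mutants' responses. It holds no spread of the WT response, which came from 1 pair of arrays. AT5G55450 went from 6.46 to 5.31 in WT, from 6.74 to 7.17 in atnp01 and from 6.27 to 6.60 in atnp02, an interaction of 1.53 (SE 0.15, adjusted p = 0.0226 in limma). EXPA8 and EXPA4, with interactions of -1.12 and -1.23, passed when adjusted over the list alone, but not over all genes (adjusted p = 0.0527 and 0.0895). RING1 had an interaction of 1.45 (adjusted p = 0.206) and CHI of 1.55 (adjusted p = 0.321).

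There were 210 genes at an unadjusted p under 0.05 for this interaction. The call of AT5G55450 was lost in fits without the intensity trend, with lower or no floor, and after loess normalization. Camera gave adjusted p of 1.83e-08 for the plastid-encoded genes (median 0.18) and 0.000253 for the expansin and xyloglucan endotransglucosylase list (median -1.12). The glucosinolate list (median 0.33) had a camera adjusted p of 0.0234. Each of these lists had a camera adjusted p of 0.639 with an estimated correlation. With 1 residual degree of freedom, the residuals of any pair of genes can only agree or oppose fully. The estimated correlation therefore cannot decide whether these calls hold.

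**Figure D4:**
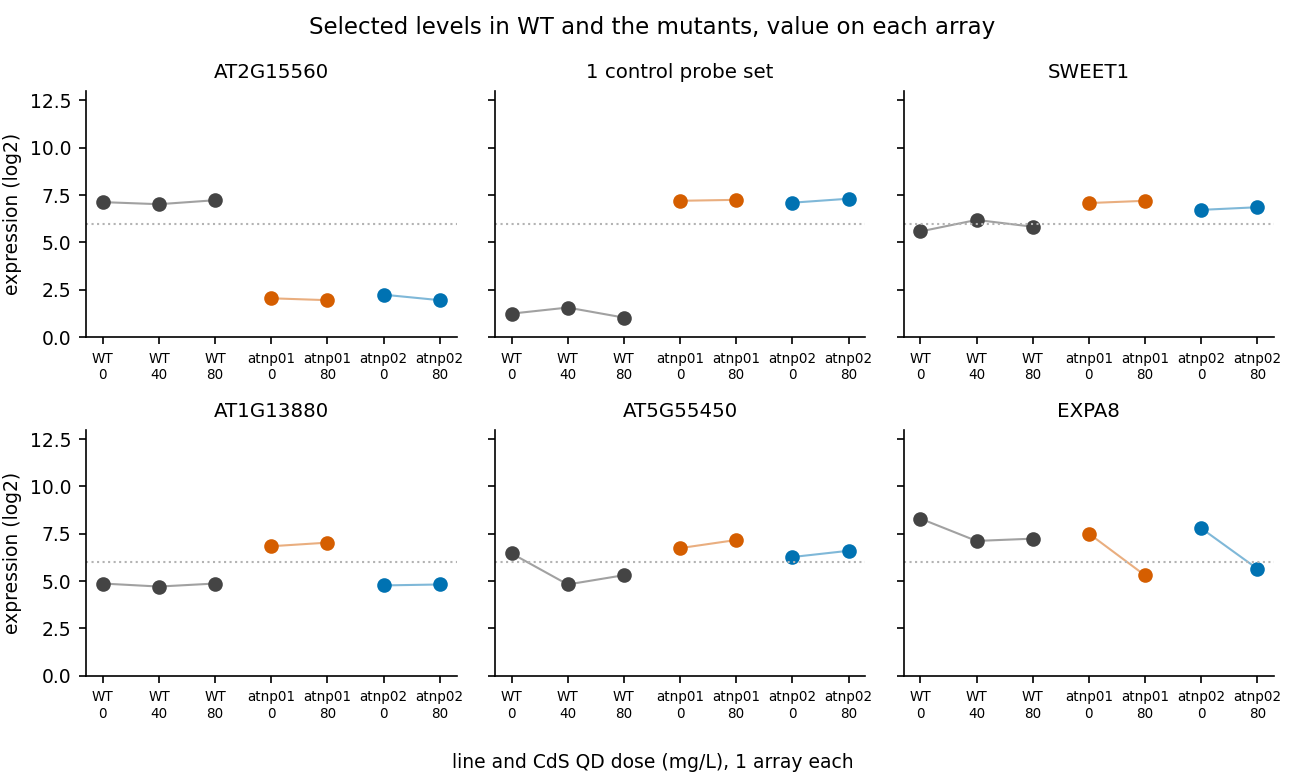
Expression (log2, y axis) of 5 genes and 1 control probe set on each of the 7 arrays (x axis, line and dose in mg/L), with the floor of log2 6 dotted. AT2G15560 was at 7.13 in WT and 2.05 in atnp01 without QDs, while EXPA8 was at 7.24 in WT, 5.30 in atnp01 and 5.65 in atnp02 at 80 mg/L.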

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

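All explanation tests in this part were chosen after the result was seen, except the correlations between mutants, which were set beforehand. The response of AT5G55450 to 80 mg/L differed between the mutants and WT by 1.53, a difference between groups under the same contrast.

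AT2G15560 and 1 control probe set separated both mutants from WT at every dose. The control probe set, which no gene comparison used, was at 1.24, 1.56 and 1.03 on the WT arrays and at 7.10 or higher on the 4 mutant arrays. The sequence that it measures is not given in the sources used here, so its level cannot be read as expression of a plant gene. Loss of a segment that spans the measured neighbours of AT2G15560 is argued against, since the 10 nearest measured genes had a median mutant minus WT difference of -0.02. A wide background shared by both mutants may account for both levels, and the 2 correlations between mutants without shared arrays were 0.256 and 0.074, of which the lower met the bound set beforehand against it. That bound was ill chosen, as atnp01 and atnp02 correlated with themselves across doses at 0.317 and 0.126, so the explanation stays open. A sequence difference under the probes cannot be told apart from a real loss of expression, because 1 probe set measured the gene, and a biological difference between mutants and WT stays open.

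On the atnp02 80 mg/L array, 12 probe sets not assigned to 1 gene lay at least 3 log2 above each other array, a signal outside the gene comparisons that no other array showed. Named genes with the same pattern were dim, led by AT2G15010 (4.77 against at most 1.27 elsewhere), AT1G03890 (4.34), AT1G47540 (4.34) and AT5G38160 (4.24). Array scaling was not decided, since the difference of the median gene of this array from the others, -0.01, was set by the normalization. Maturing seeds in the atnp02 80 mg/L sample are a candidate explanation that stays open, because of 35 marker genes written down before this test 5 were measured, and 1 of these, the oleosin gene AT3G01570, was at least 1 log2 above each other array, as were 25 of all 13356 genes (0.19%). OLEO3 was higher by 0.85 and PAP85 by 0.42, while M17 differed by -0.15 and BZIP53, which other tissues express, by -0.07.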

How the results depend on the processing

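The floor of log2 4, the fits on all probe sets and the overlap without atnp02 were chosen only after the result was seen. Quantile normalization, loess, centring, averaged probe sets and leaving out _s_at and _x_at probe sets kept each count of the single comparisons within 1.5 times. Counts moved with thresholds, by construction. In the order WT 80, WT 40, atnp01 and atnp02 against their own 0 mg/L, then atnp01 and atnp02 against WT at 0 and at 80 mg/L, at least 1.5-fold gave 361, 387, 515, 495, 49, 20, 75 and 65 genes, and at least 3-fold gave 58, 48, 91, 95, 3, 1, 5 and 3. No floor gave 509, 478, 698, 798, 63, 32, 137 and 118, a floor of log2 8 gave 38, 34, 48, 49, 1, 0, 2 and 1, a floor of log2 4 gave 345, 340, 518, 545, 35, 11, 90 and 72, and all probe sets gave 348, 307, 506, 513, 17, 8, 51 and 55. The count for 80 mg/L across lines was 2552 with no floor, 2478 with a floor of log2 4, 2583 over all probe sets and 780 with a linear dose term, and with each line left out it lay between 798 and 1183. For atnp01 against WT, robust moderation gave 6 genes, a floor of log2 4 gave 15, and leaving out atnp02 gave 15. For atnp02 against WT, the fit without the trend gave 2, robust moderation 3, a floor of log2 4 gave 3, all probe sets 0 (318 at an unadjusted p under 0.05), and leaving out atnp01 gave 2. For the interaction, robust moderation gave 3, a mean of log2 6 gave 12, averaged probe sets 4, leaving out _s_at and _x_at probe sets 4, and no trend, no floor, a floor of log2 4, all probe sets and loess gave 0 (175, 678, 457, 399 and 212 at an unadjusted p under 0.05). The interaction could not be fitted with a line left out. At 1.5-fold, 315 genes were shared by the 3 lines, and 279 by both WT doses with no floor. Lists outside the middle 95% of random lists numbered 25 of 80, and 39 with no floor. Of 11 camera calls at the preset correlation, 0 held with an estimated correlation. Few residual degrees of freedom leave that estimate imprecise. The test then also takes them as its reference, so that few lists could pass. For the effect of 80 mg/L, the camera p of the reactive oxygen list went from 0.00526 to 0.106, though its estimated correlation was -0.259. The loss of these calls therefore does not show that correlation between genes accounts for them. Beyond the thresholds, the cause was not tested. Without atnp02, WT and atnp01 shared 152 genes. Of 1609 values of genes in the limma tests, 62 lost and 13 gained a call, and of 240 list medians 17 moved. No named gene or called list median reversed its direction. Signal near background limits the dim genes.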

Other observations

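The test of other splits and the tests of plastid genes in this part were chosen only after the result was seen. Some genes below the floor differed between doses, mostly from values near background, so that their differences have no exact size. BHLH101, a regulator of the iron-deficiency response, was higher at 80 mg/L by 3.84 in WT, 2.65 in atnp01 and 2.45 in atnp02, and by 0.39 at 40 mg/L in WT. As a list, the iron-deficiency genes did not follow. The 5 annotated members, BHLH101 among them, had medians of 0.258, -0.233 and 0 in WT, atnp01 and atnp02 at 80 mg/L. In the same order PYE was higher by 0.58, 0.74 and 0.73, and by 0.15 at 40 mg/L in WT. AT3G13610 differed by -1.09, -1.42 and -0.62, AT3G12900 by -0.18, -0.36 and -0.36, and BGLU42 by 0.26, -0.23 and 0. The thionin gene THI2.1, of jasmonate response, was higher by 4.52 in WT at 80 mg/L, by 4.05 at 40 mg/L and by 4.07 in atnp02, but differed by -0.95 in atnp01. COR15A was higher by 2.66, 1.56 and 3.07 in WT, atnp01 and atnp02 and differed by -0.07 at 40 mg/L. These genes were named after their values were seen.

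The 5 heat shock genes on the annotation had a median of 1.372 at 40 mg/L in WT. At 80 mg/L their medians were 0.479 in WT, 0.029 in atnp01 and 0.779 in atnp02. In WT, AT5G48570 was higher by 1.53 at 40 mg/L and by 0.20 at 80 mg/L. AT1G53540 was at 1.18, near background, at 0 mg/L, at 4.62 at 40 mg/L and at 2.95 at 80 mg/L in WT. DFR, of anthocyanin synthesis, was higher by 2.07 at 40 mg/L and by 1.04 at 80 mg/L in WT, and by 2.38 in atnp01 and 1.71 in atnp02 at 80 mg/L. The zinc transporter gene ZIP9 differed by 0.27, 0.69 and -0.32 at 80 mg/L in WT, atnp01 and atnp02. The flower marker AT5G07230 was higher by 2.1, 1.13 and 1.78. All these values are below the floor and from single arrays. The 16 mitochondrion-encoded genes, of which 1 reached the floor, had medians of 0.224, 0.198 and 0.184 at 80 mg/L in WT, atnp01 and atnp02, each at percentile 99.6, and of 0.241 at 40 mg/L in WT, at percentile 99.8. Among them cox1 was higher at 80 mg/L by 1.55, 1.37 and 1.59. In the same lines ccb382 was at 4.17, 3.28 and 3.55 without QDs and at 5.66, 5.63 and 5.68 at 80 mg/L. The medians of the mitochondrion-encoded list are small and rest mostly on genes below the floor, so they were not interpreted.

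The differences of plastid-encoded genes at 80 mg/L were alike in the 3 lines, with correlations across these genes of 0.9 to 0.959. Array scaling is argued against, since these genes exceeded nuclear genes of the same brightness by at least 0.59 in every line and normalization. A larger share of plastid RNA that raised all these genes by about 1 factor, as the only cause, is argued against too. The changes had an SD of 0.90 where the median SE of 1 gene was 0.12. That SE is the spread between lines and holds no differences in response between probe sets. A larger share that probe sets register unevenly was not tested. For less intact RNA, the difference between 3' and 5' control probe sets changed by a mean of 0.04 (SD 0.20 over 18 values, from 6 control pairs in 3 lines). Single values ran both ways, from -0.32 in WT to 0.40 in atnp01. These controls measure actin, GAPDH and ubiquitin transcripts and no plastid transcript, so they cannot decide whether plastid RNA was less intact. Adjacent plastid genes changed more alike than in shuffled gene orders, at percentile 2.92, which is consistent with an effect on cotranscribed neighbours. As the poly-A spike-in controls were also lower on the exposed arrays, a difference in amplification stays open beside the exposure itself.

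The count of 1202 genes at 80 mg/L came from 1 of the 10 splits of the 6 arrays into 3 and 3, and the highest of the other splits gave 0. With 10 splits the share cannot fall under 0.05. Each other split put exposed and unexposed arrays on both sides, so the differences between doses entered its error. Few calls would follow from that alone, so the splits cannot decide whether the 1202 genes arose by chance.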
